A study of Drosophila melanogaster with 4 samples.

How the data were processed

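Chromatin of Kc167 cells, a female Drosophila melanogaster line derived from embryos, was cross-linked with formaldehyde, sonicated and either immunoprecipitated with a rabbit antibody against Sin3A or kept as input DNA, per the labels' protocols. The labels give 2 immunoprecipitated libraries and 2 input libraries, and nothing in them says whether replicates came from separate cultures. CASAVA (versions 1.7.0.2 and 1.7.0.3), BWA and MACS2 are named in the submitters' processing notes together with the build BDGP5, without their settings. Per the file headers the coordinates are FlyBase release 5, and the peaks carry MACS as their source. Whether reads of the replicates were pooled before peak calling, which threshold was used and how duplicate reads were treated are not given in the sources used here.

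The deposited file is 1 list of peaks for the whole series. Each peak has a start and an end, 1-based, and a score given by the authors' peak caller. Neither the header nor the labels name the statistic behind the deposited score. It was therefore checked against the values. Of the deposited scores, 64 were shared by at least 6 peaks each. A series of −log10 upper-tail probabilities of a Poisson distribution with a single mean was fitted to them, with the mean as the only free number. At a mean of 61.3, 63 of the 64 tied scores lay within 0.01 of a value of the series. With the mean fitted on every other tied score, 31 of the 32 held out also did. Between the 58 pairs of tied scores that were adjacent on the fitted series, the steps ranged from 0.26 at low scores to 0.47 at high ones, whereas a linear fold would give equal steps. The deposited score was read accordingly as −log10 of a Poisson probability, an inference from the values. A peak whose score lay on the series is described below as scored against the common background. There were 1019 such peaks (74.3%), against the 5.49% that the tolerance on both sides takes up of the steps between values, and the other 352 are described as scored off it. The latter include the 15 peaks at the tied score that was missed, 17.23, which lay 0.015 from the series and is probably one of its values. A tolerance of 0.02 was therefore also tried, chosen after seeing the data.

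No values per library were used, so no replicate error, total read count or per-library interval can be given, and the depth is unknown. Intervals and p-values describe the peaks of this list and not the spread between cultures. The gene table used here is release 6, a different build from that of the peaks. It served only to count genes per chromosome arm, and peaks were not assigned to genes. The planned comparisons with start sites, annotation classes, fixed gene lists and sequence motifs need a genome of release 5 and were not run. For this reason no gene is named from a position.

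Before the data were examined, 4 comparisons that need only the peak list were fixed. The first set the number of peaks on each of the 6 arms (2L, 2R, 3L, 3R, X and 4) against the arm's share of protein-coding genes by a two-sided exact binomial test. Gene share was the fixed fallback, since the plan put arm length first where the headers or a same-build reference gave it. Benjamini-Hochberg adjustment was over the 6 arms, and intervals are exact Clopper-Pearson 95% intervals. The second compared the median score and width of peaks on X and on the 4 large autosomal arms by two-sided permutation tests (100000 permutations). The third set the distance between neighbouring midpoints and the share of peaks with a neighbour within 5 kb against 10000 uniform placements between the first and last peak of each arm. The fourth correlated score with width across peaks by permutation (100000). Peaks on heterochromatic and unplaced sequences were left out of the first 3. The peaks named are the 5 with the highest score, the highest of each arm and the 3 widest, as fixed beforehand. The rule's genes at start sites were not available for the reason given above.

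Alternatives fixed beforehand were the 50% and the 25% of the peaks with the highest score, heterochromatic sequences added to their arm, all annotated genes as denominator, peaks within 1 kb merged, other neighbour distances (1 kb and 20 kb), the inner part of each arm (5th to 95th percentile of positions), log10 values, and each autosomal arm left out. Chosen after seeing the data were the distance between the first and last peak as denominator, merging within 20 kb, X left out, 10000 bootstrap draws of 1 Mb windows, and placement inside the same 1 Mb windows. All computations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. The methods were tested on simulated data. The spacing test called 3.50% of 200 lists of 1273 unclustered peaks. The arm test called any arm in 2.80% of 500 lists drawn by gene share, and called X in 82.4% of 500 lists in which X was raised 1.3 times. Peaks in the lists of the arm test were drawn independently, so these rates do not cover peaks that lie in groups. A score series simulated with a mean of 47.5 gave back 47.5.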

Results

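Binding of Sin3A along the genome was measured by chromatin immunoprecipitation and sequencing in Kc167, a Drosophila cell line derived from embryos and labelled female. Sin3A is the scaffold of a corepressor complex that carries the histone deacetylase HDAC1. The design compared 2 immunoprecipitated libraries with 2 input libraries, and the deposited result is a single list of 1371 peaks. The peaks together covered 573 kb. Their median width was 361 bp, with quartiles of 267 and 508 bp and a range from 201 to 2110 bp. The authors' peak score had a median of 17.1 and ranged from 6.36 to 131. Because the list holds no values per library, none of the values carries a replicate error.

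Sin3A peaks were found on all of the 6 chromosome arms examined. The 5 highest-scoring peaks lay on X, 2R and 3R. The highest was on X at 10638951 to 10639502 (release 5 coordinates throughout), with a score of 131 and a width of 552 bp. The second lay on 2R at 8756776 to 8757900, with a score of 128. The third lay on the same arm at 8767177 to 8767992, with a score of 115, so that this stretch of 2R held 2 of the 5 highest peaks. The fourth was on 3R at 8251552 to 8252205 and scored 111. The fifth was on X at 18677421 to 18678032 and scored 103, and the peak nearest to it, with a midpoint 4659 bp away, scored 90.0. The highest peak on 3L, at 16581198 to 16581699, scored 101 and ranked 7 in the list. On 2L the highest peak, at 13176654 to 13177288, scored 73.1 and ranked 21. This peak, the third-ranked one on 2R and the peak on X that scored 90.0 were scored off the common background. Their scores and ranks are therefore compared across different backgrounds. Chromosome 4 had its highest peak at 681000 to 681746, with a score of 32.6 and rank 237. The widest peaks were at 3L 15534349 to 15536458 (2110 bp, score 35.9), X 14978604 to 14980322 (1719 bp, score 42.8) and X 5314380 to 5315868 (1489 bp, score 25.1).

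**Figure D1:**
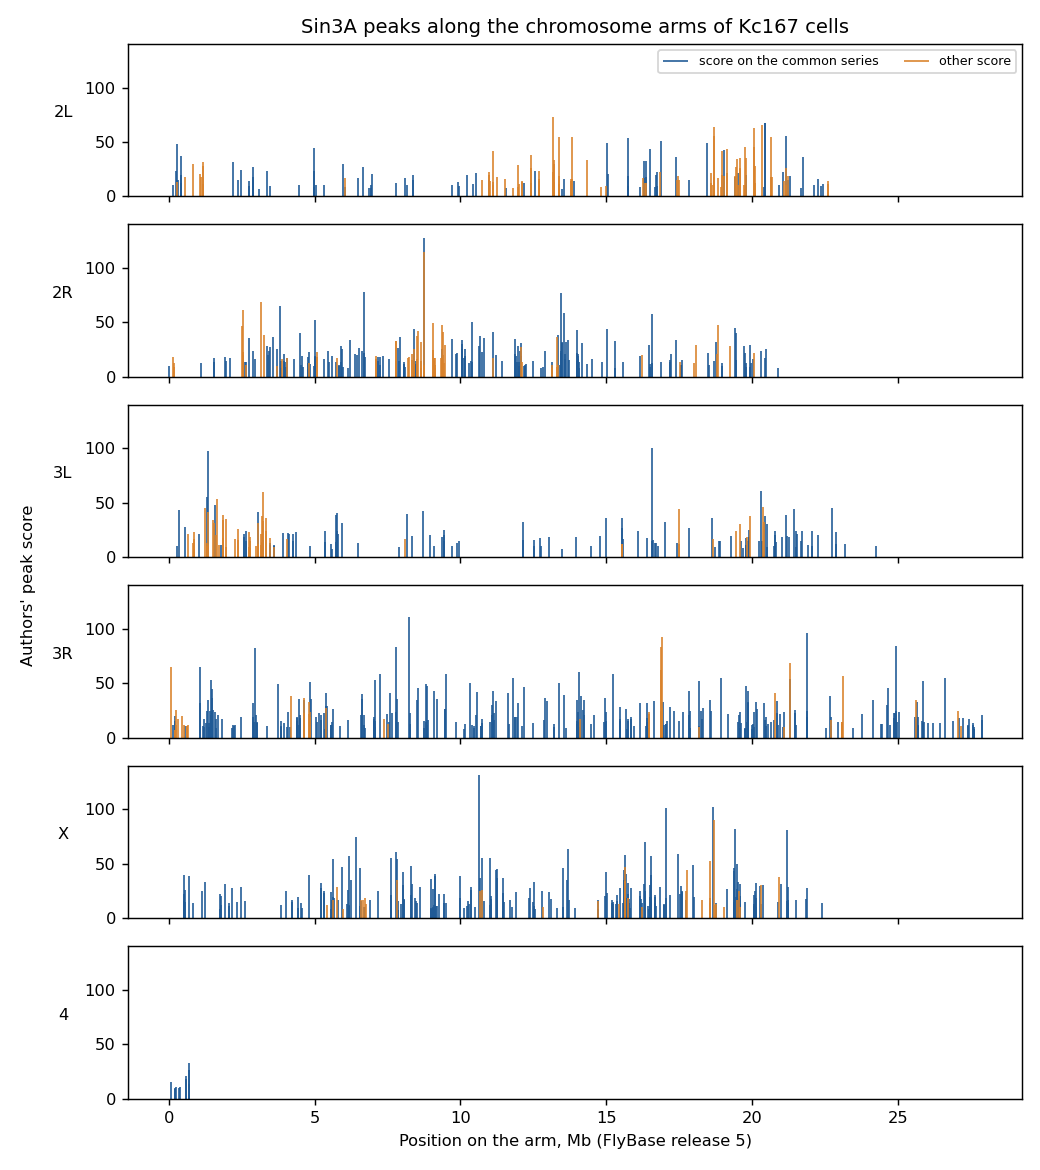
Position in Mb (release 5, horizontal axis) and authors' peak score (vertical axis) of the peaks on the 6 arms, one panel per arm and one line per peak. Blue lines are peaks scored against the common background and orange lines the others, which made up 50.5% of the peaks on 2L and 11.5% on X.

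The X chromosome carried more Sin3A peaks than its share of genes, and the left arms of both large autosomes carried fewer. On X there were 286 peaks against 201 expected, a ratio of 1.43 (95% interval 1.28 to 1.58), or 13.0 peaks per 100 protein-coding genes. The 3R arm held 356 peaks against 311 expected, a ratio of 1.15 (1.05 to 1.25). On 2L there were 188 peaks against 243 expected (ratio 0.774, 0.674 to 0.882), and on 3L 174 against 251 (ratio 0.694, 0.601 to 0.796). Per 100 genes this was 7.08 peaks on 2L and 6.35 on 3L. The right arm of the second chromosome, with 258 peaks against 261 expected, had a ratio of 0.990 (0.883 to 1.10). Chromosome 4 had 11 peaks against 7.32 expected, and its interval of 0.751 to 2.68 leaves both an excess and a deficit possible. By length the order of the arms was the same, but X, 3R and 2R lay closer together. Per Mb between an arm's first and last peak, X held 13.1 peaks, 3R 12.8 and 2R 12.3, against 8.38 on 2L and 7.26 on 3L. Chromosome 4 held 18.2, from its 11 peaks. With the distance between first and last peak as denominator, X lay close to 3R and 2R and its ratio fell to 1.21. That smaller excess still passed the exact test (adjusted p = 0.000814).

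In exact binomial tests adjusted over the 6 arms, X (adjusted p = 2.36e-09), 3L (5.82e-08), 2L (0.000127) and 3R (0.00551) differed from their share of genes. The 2R arm (0.890) and chromosome 4 (0.226) did not pass the threshold. Because neighbouring peaks are not independent, 1 Mb windows were also resampled within arms. The excess on 3R no longer passed in that bootstrap, in which the exact test is replaced by resampling (interval 0.994 to 1.31, adjusted p = 0.0777), while X (1.13 to 1.73, adjusted p = 0.01), 3L (0.497 to 0.898, adjusted p = 0.01) and 2L (0.593 to 0.957, adjusted p = 0.0287) did. Arm shares add up to a fixed total, so the values of the other arms were also taken without X, where 3R had a ratio of 1.24, 2L of 0.841 and 3L of 0.754.

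**Figure D2:**
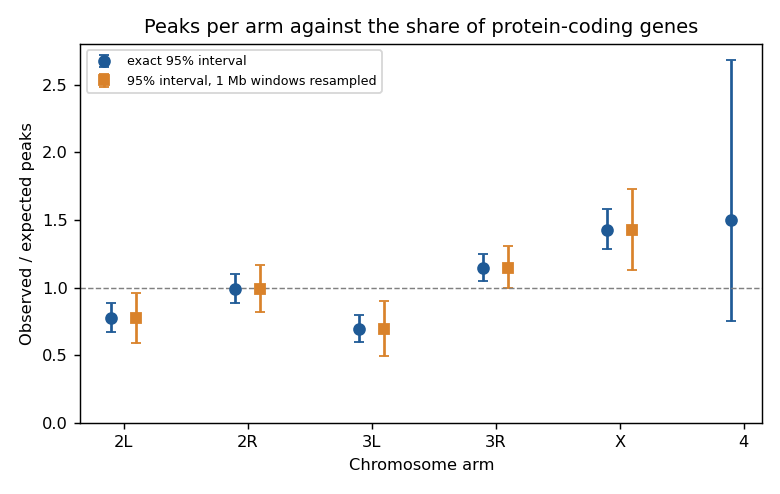
Ratio of observed to expected peaks (vertical axis) for each chromosome arm (horizontal axis), with the expectation from each arm's share of protein-coding genes and a dashed line at 1. Circles carry exact 95% intervals and squares 95% intervals from resampled 1 Mb windows (not made for chromosome 4), and X lies above 1 and 2L and 3L below 1 with both.

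The arms also differed in how their peaks had been scored. On 2L 50.5% of peaks (95% exact interval 43.2 to 57.9%) had scores off the common background, on 3L 31.6% (24.8 to 39.1%), on 2R 26.4% (21.1 to 32.2%), on 3R 13.5% (10.1 to 17.5%) and on X 11.5% (8.08 to 15.8%). These intervals cover counting error only.

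Between peaks on X and on the autosomal arms, a difference in score or width was not resolved. The score is not a peak height, and 11.5% of peaks on X and 27.3% on the autosomal arms were scored off the common background, so the scores were not all set against one background. The median score was 18.6 on X (286 peaks, quartiles 13.1 and 29.0) and 17.6 on the 4 large autosomal arms (976 peaks, quartiles 12.5 and 26.3). The difference of 0.960 had a bootstrap 95% interval from -1.08 to 2.62 and did not pass a two-sided permutation test (p = 0.289, adjusted p = 0.577). The median width was 381 bp on X and 376 bp on the autosomal arms, a difference of 5.00 bp with an interval from -19.5 to 43.5 bp (permutation p = 0.732, adjusted p = 0.732).

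Sin3A peaks lay in groups. Of the 1273 peaks on the 6 arms, 32.1% had another peak within 5 kb, against a mean of 10.6% in random placements (central 95% 8.33 to 13.0%). The median distance to the next peak was 32.2 kb, against 62.2 kb. Each of the 5 large arms had more near neighbours than placement gave. The share was 35.7% on 3R against 11.8% at random, 33.5% on 2L against 7.90%, 32.5% on X against 12.1%, 30.2% on 2R against 11.5%, and 24.7% on 3L against 6.89%. Each of these p-values was 0.0002, the smallest that 10000 placements can give in a two-sided test. Merging peaks within 1 kb of each other left 1165 regions, of which 20.1% had a neighbour within 5 kb against 9.67% in the same random placement (Monte Carlo permutation p = 0.0002). Placement was uniform along the arm and takes no account of where genes lie.

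**Figure D3:**
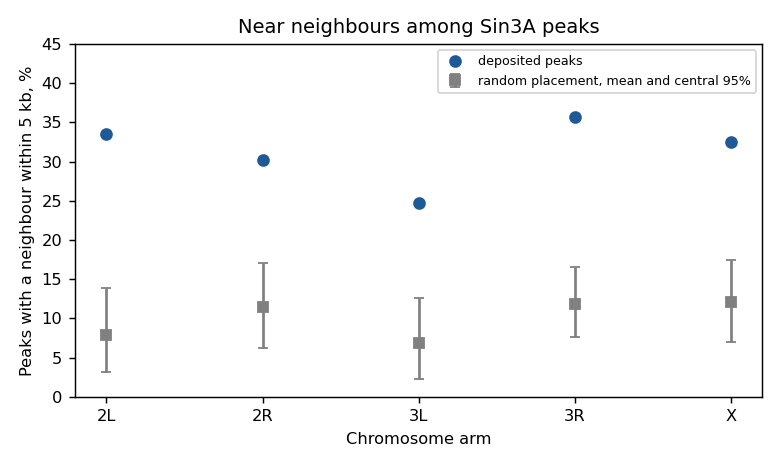
Share of peaks with another peak within 5 kb in percent (vertical axis) on the 5 large arms (horizontal axis), for the deposited peaks (circles) and for 10000 random placements (squares, mean with the central 95%). The deposited shares, from 24.7% on 3L to 35.7% on 3R, lie above the random ranges on all 5 arms.

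Higher-scoring peaks were wider. Across all 1371 peaks the Pearson correlation of score and width was 0.571 and the Spearman correlation 0.675, each with a permutation p of 1e-05, the smallest that the permutations can give (adjusting over this pair of tests leaves it unaltered). Among the 50% of the peaks with the highest score the coefficients were 0.387 and 0.483. These correlations are across peaks of 1 list, which are not independent replicates, and both measures come from the same peak call.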

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

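The test of the share off the common background was written down before its result was seen, and the tests of score and width were chosen afterwards. A signal appeared outside the arms used in the comparisons: 98 of the 1371 peaks (7.15%, exact 95% interval 5.84 to 8.64%) lay on sequences that release 5 keeps apart as heterochromatic or unplaced. Of these, 51 lay on Uextra, 28 on 3RHet, 15 on U, 3 on 3LHet and 1 on XHet, and the list names none on YHet, 2LHet or 2RHet. Their median score was 11.5 against 17.9 on the arms (two-sided permutation test, adjusted p = 4e-05), and their median width 247 bp against 376 bp (adjusted p = 2e-05). Repeated sequence assembled in too few copies would raise the input there, and the caller would then score such peaks against a local background. Scores off the common background made up 54.1% of these peaks and 23.5% of those on the arms, a difference of 30.6 percentage points (95% interval from resampled 1 Mb windows 16.7 to 40.9), which is consistent with that explanation. The share is not specific to such sequence, however, since it was 50.5% on 2L, a difference of 3.55 points from these peaks (-15.0 to 21.7). The cause stays open, as does whether Sin3A is enriched at these sequences, and no biological explanation was tested.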

How the results depend on the processing

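Of 82 recomputed values, 73 were counted as unaltered in direction and side of the threshold, and no result that had passed changed direction. The count includes results that had not passed and still did not. It also includes the shares off the common background at the other tolerance, which had no test. Resampled windows keep the ratio of the main result, so its direction could not change there. The excess on X passed in all of its 8 alternatives and the deficit on 3L in all of its 9. The deficit on 2L ended in the 25% of the peaks with the highest score (exact test, ratio 0.751, adjusted p = 0.0548), where 342 peaks remained on the arms. The excess on 3R ended in the exact test on the 50% (1.13, adjusted p = 0.0893) and on the 25% (1.15, adjusted p = 0.174) with the highest score, and in 2 settings chosen after seeing the data, merging within 20 kb (1.14, adjusted p = 0.0536) and resampled 1 Mb windows (1.15, adjusted p = 0.0777). The ratios moved little, and fewer peaks, merged regions or windows in place of peaks entered these tests. With the distance between the first and last peak as denominator, also chosen afterwards, 2R turned from a ratio of 0.990 to 1.14 and passed the threshold of the exact test (adjusted p = 0.0250). X fell from a ratio of 1.43 to 1.21, still past that threshold. By this length X lay close to 3R (1.18) and 2R, while 2L (0.774) and 3L (0.671) stayed low. Resampled windows were not run with this denominator. The 2R ratio, which had not passed, also turned above 1 with merging within 20 kb (1.02) and with X left out (1.08), without passing. The difference in median width between X and the autosomal arms turned to -2 bp with 2L left out, also without passing. The tests of spacing and of score against width passed under each alternative run, and those of score and width on X under none. With a tolerance of 0.02 the share of peaks off the common background fell on each large arm, to 47.3% on 2L and 9.44% on X, within the intervals of the first values. No paired analysis was possible because the deposited list holds no values per replicate. Leaving out replicates was not possible for the same reason. The alternatives fixed beforehand for start sites, gene lists and motifs were not run because no genome of release 5 was used here. The depth of the libraries is unknown.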

Other observations

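The tests of input background on X and of both spacing explanations were written down before their results were seen, and all other tests in this part were chosen afterwards. The density of Sin3A peaks varied along the arms. The densest 100 kb window, X 19500001 to 19600000, held 12 peaks, whereas the fullest window of the arm held 5 in the median random placement and at most 10 (permutation p = 0.0001, the smallest possible, adjusted p = 0.0005). The fullest windows of 2L, 3L and 3R also passed that permutation test over the 5 large arms, and that of 2R, with 7 peaks, did not (adjusted p = 0.0581). Next came 3R 4800001 to 4900000 and X 15700001 to 15800000 with 9 peaks each. The peaks of the densest window were not the highest, with a maximum score of 33.0. Other stretches were empty. The longest lay on 3L from 9965624 to 12131536, 2.17 Mb without a peak, against a longest gap of 0.767 Mb in the median placement (permutation test, adjusted p = 0.0005). Gaps of 1.33 Mb on 2L (8366068 to 9699381, permutation test, adjusted p = 0.00233) and 1.20 Mb on X (2626626 to 3830286, adjusted p = 0.00075) were also longer than placement gave, as was one of 0.920 Mb on 2R (adjusted p = 0.00362). The longest gap on 3R, 0.658 Mb, did not pass (permutation test, adjusted p = 0.0713).

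Peaks with a neighbour within 5 kb scored lower than isolated peaks. The median was 16.2 for 408 such peaks and 18.5 for 865 others (two-sided permutation test, adjusted p = 0.0034), and the widths of 359 and 382 bp did not differ past the threshold (adjusted p = 0.105). Both tests took peaks as independent units although near peaks come in groups, and neither was repeated on merged regions. Peaks scored on and off the common background were pooled. Scores of neighbouring peaks within 5 kb had a Spearman correlation of 0.167 over 236 pairs, which missed the threshold after adjustment over 6 tests (adjusted p = 0.0564).

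If the score is read as above, the common background is a mean pileup of 61.3, and peaks scored against it reached a median of 2.25 times that mean. The range was 1.68 to 5.48 times, 77.5% of these peaks were at or above 2 times and 13.2% at or above 3 times.

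Scores off the common background lay in blocks. Among 518 neighbouring pairs of peaks over 50 kb apart, 78.0% were of the same class, against a mean of 66.1% and a maximum of 73.9% in 10000 permutations within arms (p = 0.0001, the smallest possible). In 18 windows of 1 Mb with at least 5 peaks, at least 50% of the peaks were off it. These windows included 2L from 11 to 14 Mb and from 17 to 21 Mb, 2R from 8 to 10 Mb and 3L from 0 to 4 Mb.

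The excess of peaks on X over its share of genes, with the deficit on 2L and 3L, was set against technical explanations. Counting one cluster several times was argued against as the whole cause, since regions merged within 20 kb still gave a ratio of 1.26 on X (1.08 to 1.45, exact test, adjusted p = 0.0105). The ratio was 1.43 before merging, so clusters may account for part of the excess. Extra copies of X in this line would raise its input, but the share of peaks off the common background was lower on X than on the autosomal arms together (difference -15.7 percentage points, 95% interval from resampled 1 Mb windows -23.6 to -7.13), a gap carried by 2L, 3L and 2R and not resolved against 3R (-1.94, interval -12.4 to 7.84). This share cannot exclude extra copies, because a rise too small to move scores off the common background would leave it unaltered. A raised background on 2L and 3L might instead have hidden peaks there. This cannot be told apart from the peak list: the 13 windows of these arms in which at least 50% of the peaks were scored off the common background held 5.92 more peaks than the 33 others after centring on each arm's mean (permutation by circular shifts, adjusted p = 0.0349), but windows were classed by the peaks that had been called, those without a peak dropped out, and with at least 5 peaks per window the centred difference of 4.51 did not pass (adjusted p = 0.0676). No biological explanation was tested.

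Technical accounts of the grouping of peaks were tested. A bound region split into several peaks is argued against as the whole cause, since 20.1% of regions merged within 1 kb had a neighbour within 5 kb and the highest of the random placements gave 14.7%. Uneven density at the scale of 1 Mb is argued against in the same way, since placement inside the same 1 Mb windows gave a mean of 12.3% and at most 17.8%, below the observed 32.1%. Uneven gene density at a finer scale stays open and may account for part of it, and no biological explanation was tested.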
